A study of Mus musculus with 2 samples.

How the data were processed

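Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in BV2 cells, an immortalised mouse microglial line, with an antibody against Nr4a2 (Nurr1), an orphan nuclear receptor. Per the labels, 1 library was made from DNA after immunoprecipitation and 1 from input DNA that was not precipitated. Chromatin was prepared with an enzymatic digestion kit, per the labels' protocols. The file header's names for both libraries carry the tag H2O2, while the labels name no treatment, so the treatment of the cells is not stated further here. There were no replicates, and nothing below measures variation between cultures.

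Reads were aligned with Bowtie2 to mm10, per the submitters' processing notes. Those notes also list ChIPseeker and MACS2 2.2.6, whereas the file header names MACS 2.1.4. Per the file header, peaks were called on the 1 ChIP library against the 1 input with a p-value cutoff of 0.001, an effective genome size of 1.87e+09 bp, a fragment length of 164 bp and a tag size of 149 bp. The header states that 1 tag was kept per position and that the larger library was scaled towards the smaller. The header gives 24935872 ChIP tags, of which 20365794 remained after duplicate removal, and 29057411 input tags, of which 22520884 remained.

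The only processed file is the authors' list of 7680 peaks. Its pileup column is a coverage signal in the deposited file, the number of extended ChIP tags over the summit. The deposited −log10 p-value compares that pileup with a local background. The deposited −log10 q-value column holds values although the file header says that q would not be calculated, and it was used as given. The deposited fold enrichment is a ratio of pileup to background, each with a pseudocount of 1. This was checked on the values, since the background recovered from the fold was never below 1.786, which is the ChIP depth times the fragment length over the effective genome size. Peak width and summit position are in bp, per the file headers. These heights, folds and p-values are the authors' values and serve here only to describe, rank and filter peaks within the list.

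Genes came from a table of RefSeq records on GRCm38.p6, the assembly that mm10 names, and coordinates are mm10. The table gives gene starts and ends but no strand, exons or sequence. Transcription start sites could therefore not be placed, and the design written for promoters was run on gene ends, meaning within 1000 bp of either end of a gene record. Exons and untranslated regions were not separated. The planned search for the Nr4a binding word and the other words of a panel of 30 was not run because no genome sequence was used here, and neither was the planned exclusion of repeat-rich peaks. No annotation column of the authors was used here.

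Peak summits on chromosomes 1 to 19, X and Y were sorted into gene ends, gene bodies and the rest, using 39334 records other than pseudogenes. Shares were compared with 1000 random placements of the same number of summits on the same chromosomes, between the first and the last annotated gene, with two-sided permutation p-values adjusted by the Benjamini-Hochberg method over 3 classes. These placements include unmappable sequence. Summits shifted by 10000 bp to either side served as a local comparison added after seeing the data, with intervals from 2000 bootstrap draws of 5 Mb bins. Fold enrichment at gene ends and elsewhere was compared by a two-sided permutation test of medians with 100000 resamples, and of means, added later, with intervals from 2000 bootstrap draws of peaks.

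In all, 26 gene lists were fixed before the data were examined, and 566 of their 568 entries matched a coding gene by symbol or synonym. For each list the share of genes with a gene-end peak was compared with all other coding genes of 21887 by a two-sided Fisher's exact test, adjusted over the lists. The share that was the nearest coding gene, by gene end, of at least 1 peak was compared with 10000 random lists matched on deciles of gene territory, the stretch over which a gene's ends are the nearest. Added later, lists were also matched on deciles of territory crossed with deciles of peak density in 5 Mb bins, with exact p-values from the hypergeometric distribution. Rank correlations over 5 Mb bins were taken within chromosomes and tested with 10000 permutations, and the one with coding genes, added later, carries an interval from 2000 bootstrap draws of chromosomes. Peaks per Mb used the span between the first and the last annotated gene of a chromosome. Shares carry exact Clopper-Pearson 95% intervals and densities exact Poisson 95% intervals, which cover counting error only. All tests treat peaks or genes of this single list as units and say nothing of other cultures.

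Genes were named by a rule fixed before the data were examined. It took the 10 peaks of highest fold on chromosomes 1 to 19 and X, the 10 gene-end peaks of highest fold, up to 4 members per list, and 25 fixed genes reported with or without a peak. Examples from these are given in the text. Alternatives were a q of at most 0.001, a fold of 5 or more, chromosomes 1 to 19 and X only, the peak centre, overlap of the peak interval by 1 bp, a window of 3000 bp, coding genes only, other strength measures, another gene background, a distance limit of 100000 bp and, added later, the removal of peaks with pileup over 30 and further matching. Chance peaks were simulated by placing tags at random at the depths in the header and calling them by the header's rule, over 200 Mb per setting.

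On simulated summits with 400 planted at gene ends, the placement test returned a gene-end share of 10.04% where 9.88% was expected, and random summits gave a permutation p of 0.776. In the list step on 21887 coding genes, a list with 10 planted members was called and random summits gave 0 calls. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.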

Results

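The data comprised 1 anti-Nr4a2 ChIP library and 1 input library from BV2 microglial cells, summarised as a single list of peaks of the ChIP over the input. Nr4a2 is a transcription factor known for its role in midbrain dopamine neurons and for restraining inflammatory genes in glia. The question was where in the genome the anti-Nr4a2 antibody enriched DNA. After duplicate removal the ChIP library held 20365794 tags and the input 22520884. With 1 library of each kind there were no replicates, so every value below stands without a measure of variation between cultures.

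The strongest peak lay in a gene-poor part of chromosome X, at 128363452 to 128363797. It had a pileup of 38 tags, a fold enrichment of 10.5 and a −log10 q of 21.1. Its summit was inside no annotated gene, with pseudogenes left out, and the nearest end of a coding gene, Cldn34c4, a claudin-like gene, was 627 kb away. It was the only peak of 10-fold or more. The next peaks by fold were 26.0 kb from Cdh12, a cadherin gene, and inside Svbp, which encodes a partner of the vasohibins, both at 6.76-fold and 18 tags. A peak of 6.46-fold lay inside Plin2, which encodes a lipid droplet coat protein, on chromosome 4 at 86638851 to 86639046. Peaks nearest to Flrt2 and Tbc1d22a also reached 6.46-fold, but their summits were 988 kb and 491 kb from those genes. Peaks nearest to Ppm1f, Ncs1, Ndufb3 and Mfsd14a had folds of 6.44, 6.42, 6.41 and 6.20.

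Most of the list was far weaker than these peaks. The median peak had a summit pileup of 10 tags, a fold enrichment of 3.59 and a width of 190 bp, and 2289 of the 7680 peaks had the minimum width of 164 bp. In 3788 peaks (49.3%, 95% interval 48.2 to 50.5) the background was the genome-wide value of 1.786 tags, to within 0.002. By the deposited q-values, 3887 peaks (50.6%) had a q of at most 0.05, 1183 (15.4%) a q of at most 0.01 and 188 (2.45%, 95% interval 2.11 to 2.82) a q of at most 0.001. A fold of 5 or more was reached by 291 peaks (3.79%). Apart from the peak on chromosome X, the 15 peaks with a pileup over 30 tags had backgrounds of 8.14 tags or more, set by the input. The highest, on chromosome 9 at 35305299 to 35305563, had 328 tags over a background of 273.1 and a fold of only 1.2.

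**Figure D1:**
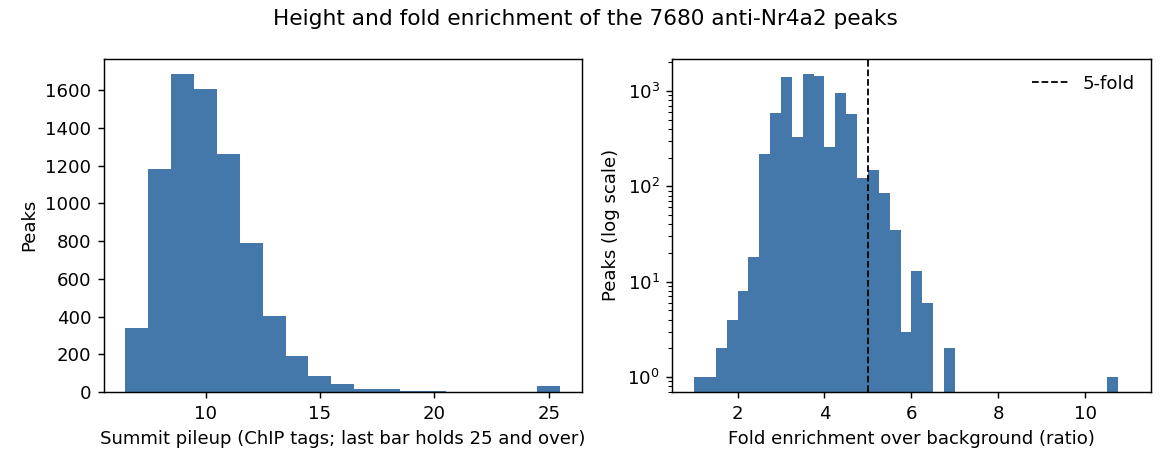
Left, number of peaks by summit pileup in ChIP tags, with all peaks of 25 tags and over in the last bar. Right, number of peaks by fold enrichment over background, on a log count axis, with a dashed line at 5-fold; the median is 3.59 and a single peak exceeds 10-fold.

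Peaks were more frequent at gene ends than random positions were. Of 7652 summits on chromosomes 1 to 19, X and Y, 624 (8.16%, 95% interval 7.55 to 8.79) lay within 1000 bp of either end of a gene, against 4.90% ± 0.24 (SD over 1000 placements) of random positions. The ratio was 1.66 with an adjusted permutation p of 0.002, the smallest these placements can give. For coding genes alone the shares were 5.96% and 2.89%, a ratio of 2.06. The ratio was highest at 100 to 250 bp from a gene end, at 2.22 (95% interval 1.86 to 2.63), and it was 1.40 (1.23 to 1.58) at 500 to 1000 bp. Beyond 100 kb from any gene end it was 0.625 (0.587 to 0.666). Against summits shifted by 10000 bp, which lie in the same neighbourhood, the ratio at gene ends was 1.41 (1.29 to 1.55).

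Gene bodies held 47.2% of summits and regions between genes 44.6%, against 42.7% and 52.4% of random positions. The direction for gene bodies depended on the comparison, since the shifted summits lay inside genes slightly more often, at 48.1%, and the ratio became 0.98 (0.965 to 0.996). The share between genes was below both comparisons, with ratios of 0.852 and 0.968. The classes together hold all placed summits, so an excess at gene ends lowers the other shares combined. Their small falls against shifted summits are therefore not separate results. Among the 183 placed peaks with a q of at most 0.001, 14 (7.65%, 95% interval 4.25 to 12.5) were at gene ends, a ratio of 1.56 with an adjusted permutation p of 0.162, so an excess was not detectable with so few peaks.

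**Figure D2:**
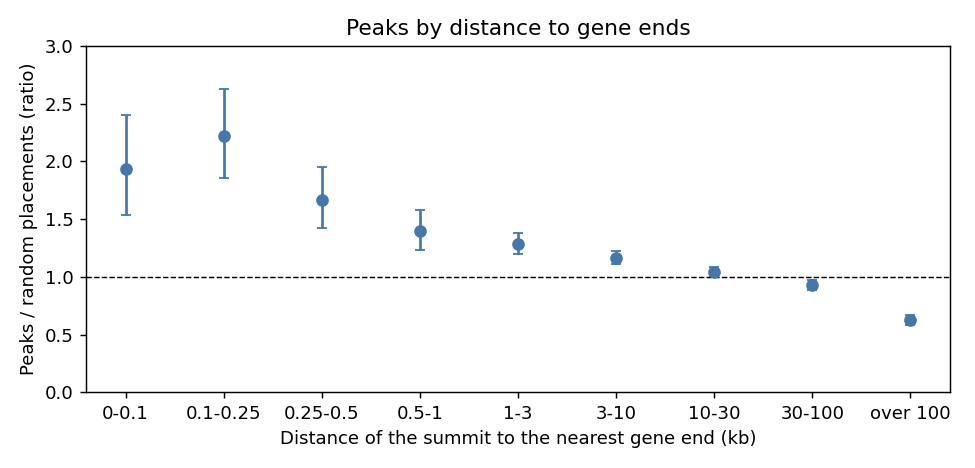
Ratio of observed peaks to the mean of random placements, by distance of the summit to the nearest gene end in kb. Points are ratios with exact Poisson 95% intervals, the dashed line marks 1, and the ratio falls from about 2 near gene ends, with 2.22 at 0.1 to 0.25 kb, to 0.625 beyond 100 kb.

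The gene-end peaks of highest fold were at Svbp (6.76-fold), Slc35b1 and Ipo13 (both 6.05-fold), Fmnl3 (5.61-fold) and Trp53inp2 (5.58-fold). Ipo13 encodes an importin, Slc35b1 a nucleotide sugar transporter family member, Fmnl3 a formin that acts on actin, and Trp53inp2 an autophagy factor. They were followed by Prex1 (5.53-fold), a Rac exchange factor, Rad17 (5.50-fold), a DNA damage checkpoint factor, and Brat1, Cnst and Nudt8 (each 5.38-fold). Summits lay 134 bp from the end of Svbp, 100 bp from Slc35b1, 57 bp from Ipo13, 37 bp from Fmnl3, 138 bp from Trp53inp2 and 87 bp from Rad17. Each of these peaks had between 14 and 18 ChIP tags. The peak at Cnst also lay 277 bp from Tfb2m, a mitochondrial transcription factor. Other genes also had an end within 1000 bp of these summits: Prpf40b for the peak at Fmnl3, Taf9 and Ak6 for that at Rad17, and Tbx10 for that at Nudt8. No difference in strength was detected between the 624 gene-end peaks and the 7028 others. The median fold was 3.59 in both sets, but 913 peaks (11.9%) lie within 0.005 of the median, so the permutation test of these medians (p = 1) says little. The mean fold was 3.71 at gene ends and 3.76 elsewhere, a difference of -0.0474 (95% interval -0.0966 to 0.005, permutation p = 0.0734). The median −log10 p was 4.79 at gene ends and 5.17 elsewhere (permutation p = 0.241).

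In all, 516 of 21887 coding genes (2.36%, 95% interval 2.16 to 2.57) had a peak at an end. Of the 25 genes fixed in advance as of interest for Nr4a2, microglia and oxidative stress, 1 had a gene-end peak, against 0.589 expected at that rate. This was Nfe2l2, which encodes the antioxidant regulator NRF2, with a peak of 9 tags and 3.59-fold whose summit was 624 bp outside the gene on chromosome 2 at 75705185 to 75705348. Its q was above 0.05, with a −log10 q of 1.08. Another 6 genes had a peak inside them but not at an end. These were Rxra (4.27-fold), which encodes a dimer partner of Nr4a2, the microglial receptor genes Csf1r (4.31-fold) and Cx3cr1 (3.59-fold), the dopamine transporter gene Slc6a3 (3.59-fold), the corepressor gene Rcor1 (2.96-fold) and the cystine transporter gene Slc7a11 (3.14-fold). Of these, the peaks in Cx3cr1, Slc6a3 and Slc7a11 (−log10 q of 1.08 each) and in Rcor1 (0.76) had a q above 0.05.

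The other 18 of these genes had no peak inside or at an end. The nearest peak was 384 kb from Nr4a2 itself, 34.1 kb from Nr4a1 and 328 kb from Nr4a3. It was 229.6 kb from Th, the tyrosine hydroxylase gene, and 88.1 kb from Slc18a2, the vesicular monoamine transporter gene. Among inflammatory genes, the closest peak to Tnf was at 3.77 kb, but it lay nearer to an end of another coding gene. That peak was 2.96-fold with a −log10 q of 0.76, so a q above 0.05. The nearest peaks were 245 kb from Il1b, 500.3 kb from Il6 and 52.2 kb from Nos2. Nfkbia, which encodes an inhibitor of NF-κB, was 73.8 kb from its nearest peak. Among stress genes, Hmox1, Nqo1, Gpx4 and Cdkn1a were 62.1 kb, 84.9 kb, 109.8 kb and 86.7 kb from the nearest peak. The nearest peak to the myeloid factor gene Spi1 was at 21.6 kb, to Spp1 at 23.4 kb, to Fosb at 577 kb and to P2ry12 at 1682 kb.

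None of the 26 fixed gene lists passed the threshold for gene-end peaks within 1000 bp after adjustment by Fisher's exact test, and 2 lists had an unadjusted p under 0.05. Within 3000 bp the spliceosome and RNA processing list passed, with 6 of 26 genes against 5.10% of others (adjusted Fisher exact p = 0.044). That p was adjusted over the lists but not over the settings run. Peaks nearest to Hnrnpu, Hnrnpc and Sf3a1 also lay within 3000 bp of an end, so this call and the nearest-gene call below share peaks. Within 1000 bp the list had 2 of 26, Srsf10 and Ddx5, against 2.35% (adjusted Fisher exact p = 0.54). In the replication-dependent histone list 3 of 18 genes had one, against 2.35% of other genes (unadjusted Fisher exact p = 0.00817, adjusted p = 0.164). These were H3c13 at 4.93-fold, and H3c1 and H4c1, which shared a peak of 3.59-fold; histone genes have near-identical copies, so reads there are uncertain. In the unfolded protein response and heat shock list it was 3 of 21 (unadjusted Fisher exact p = 0.0126, adjusted p = 0.164), namely the chaperone genes Hsp90ab1 (4.55-fold), Hsp90aa1 (4.36-fold) and Dnajb9 (3.56-fold). The peak at Hsp90ab1 lay inside its neighbour Slc35b2. The peaks at Dnajb9 and at H3c1 and H4c1 (−log10 q of 1.08 each), and at Ddx5 (0.76), had a q above 0.05. Immediate early genes had 2 of 22, at Jun (3.95-fold) and Dusp5 (3.83-fold), with an adjusted p of 0.489.

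No gene-end peak was found at any of the 26 microglia identity genes, for which the exact 95% upper limit is 13.2%, the 20 NF-κB pathway genes (upper limit 16.8%), the 16 anti-inflammatory genes (20.6%) or the 14 dopamine neuron targets (23.2%). The same held for the 11 genes of the NR4A family and partners, and for the iron and ferroptosis, apoptosis, interferon response, neuron, lymphocyte and olfactory receptor lists. The proinflammatory list had 1 of 24, Cd40, a co-stimulatory receptor gene, at 3.92-fold. Oxidative stress defence had 1 of 25, Nfe2l2, and p53 and DNA damage 1 of 22, Ccng1 at 3.59-fold. Cell cycle had 1 of 30, the mitotic kinase gene Aurkb at 4.63-fold, and glycolysis and hypoxia 1 of 20, Vegfa at 2.87-fold. Ribosomal protein genes had 3 of 46, at Rps2, Rpl24 and Rps24 with folds of 4.63, 3.23 and 3.20. The peak at Rps2 was also 473 bp from Ndufb10, the only one of 40 oxidative phosphorylation genes with a gene-end peak. Mitochondrial quality and biogenesis had 2 of 20, Tfb2m and Fis1. Autophagy and lysosome had 1 of 22, Map1lc3b at 4.56-fold, the glial marker list 1 of 18, Pdgfra, and the liver list 1 of 16, Fgb. The peaks at Nfe2l2, Ccng1, Vegfa, Rpl24, Rps24, Fis1 and Fgb had a q above 0.05, with −log10 q from 0.54 to 1.08.

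By nearest gene, the spliceosome and RNA processing list stood apart. Of its 26 genes, 10 were the nearest coding gene of at least 1 peak, against a mean of 3.12 in random lists matched on gene territory (adjusted permutation p = 0.0156 over 26 lists). The naming rule put members with a gene-end peak first and then ranked by fold. It gave Srsf10 (3.77-fold, 0.251 kb from an end) and Ddx5 (3.23-fold, 0.351 kb), followed by Tra2b (5.70-fold, 3.32 kb) and Sf3b2 (4.39-fold, 5.28 kb). The peak at Ddx5 had 8 tags and a −log10 q of 0.76, so a q above 0.05, and lay inside its neighbour Cep95. Srsf10, Tra2b and Sf3b2 encode splicing factors and Ddx5 an RNA helicase. Listed after their values were seen, the others were Hnrnpu, Sf3a1, Sf3b1, Hnrnpc, U2af1 and Srsf6. Their folds ran from 2.85 with 7 tags at Sf3b1 to 4.29 with 12 tags at Hnrnpu. Hnrnpc (3.59-fold) and Srsf6 (3.02-fold, 40.4 kb from an end) had 9 tags each. Peaks with the tags and fold of those at Sf3b1 and Hnrnpc had a q above 0.05 elsewhere in the list. Examples were the peaks nearest to Ctsl and Nfe2l2, with −log10 q of 0.54 and 1.08. The call by nearest gene thus rests in part on weak peaks. With a q of at most 0.001, 1 of the 10 genes was nearest to a peak, against 0.0853 in random lists, a ratio of 11.7 (95% interval 0.297 to 59.9) with an adjusted permutation p of 1.

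Immediate early genes (9 of 22 against 4.60 in matched random lists, adjusted p = 0.25) and unfolded protein response and heat shock genes (7 of 21 against 2.92, adjusted p = 0.25) did not pass by the same permutation test. Microglia identity genes were nearest to a peak in 8 of 26 cases against 6.21, dopamine neuron targets in 8 of 14 against 4.93, and oxidative stress defence genes in 4 of 25 against 4.01, all with adjusted permutation p-values of 0.876 or more. The microglial examples of highest fold were Sall1 (5.02-fold, 321 kb away), Ptprc, Csf1r and Irf8 (each 4.31-fold). For the proinflammatory list it was 6 of 24 against 4.81, with the highest folds at Ccl4 (4.55-fold, 7.57 kb) and Tlr4 (3.95-fold, 482 kb).

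Peaks were spread very unevenly over the chromosomes. Chromosome 15 held 663 peaks, 6.38 per Mb (95% interval 5.91 to 6.89), and chromosome 6 held 47, 0.314 per Mb (0.231 to 0.418), a ratio of 20.3 (15.1 to 27.9). Chromosomes 12 and 19 had 5.76 and 5.74 per Mb, while chromosomes 10, 7 and 18 had 0.455, 1.05 and 1.12 per Mb. The median over autosomes was 2.92 per Mb, the X had 3.82 per Mb and the Y 4 peaks in total. Changes within chromosomes were abrupt. On chromosome 3, the 10 Mb bin from 30 Mb held 2 peaks, the next bin 83, the bin from 60 Mb 5 and the bin from 70 Mb 75. On chromosome 8 the bins from 30 and 40 Mb held 1 and 57 peaks. Within chromosomes, bins of 5 Mb with more coding genes held more peaks, with a rank correlation of 0.470 (95% interval 0.412 to 0.522) over 517 bins. The ratio of chromosome 15 to 6 was 10.8 (2.51 to 97.3) at a q of at most 0.001 and 11.03 (3.33 to 57.4) at 5-fold or more.

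**Figure D3:**
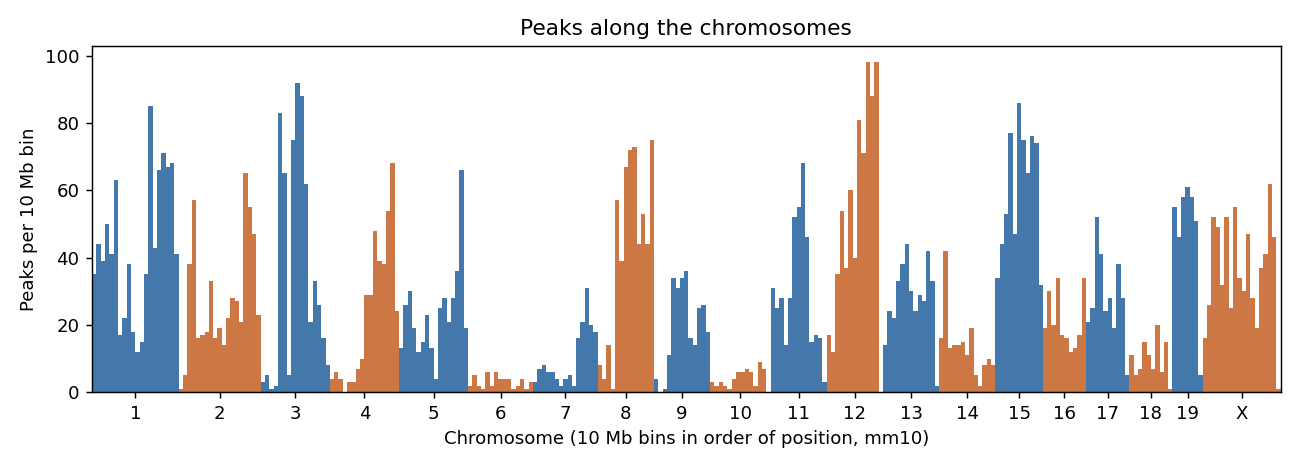
Number of peaks in each 10 Mb bin along chromosomes 1 to 19 and X, with alternating colours for neighbouring chromosomes. Chromosomes 6 and 10 are nearly empty with 47 and 58 peaks, and chromosome 3 switches between bins of 2 and 83 peaks.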

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

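The list also holds peaks outside the chromosomes used in the comparisons. There were 19 peaks on unplaced or random contigs and 9 on the mitochondrial genome, all called above the input. The strongest mitochondrial peaks had a fold of 4.98 at 5638 to 6057 and 4.55 at 13936 to 14138. No explanation was tested for these.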

How the results depend on the processing

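The number of peaks is set mainly by the threshold, with 7680 as deposited, 188 at a q of at most 0.001 and 291 at 5-fold or more. At these settings the excess at gene ends was no longer past the threshold, with ratios over random placement of 1.56 and 1.38. The ratios for gene bodies were then 1.12 and 1.04, and those between genes 0.853 and 0.932. All kept their direction, and the smaller number of peaks widens the spread of the placements by construction. Against summits shifted by 10000 bp, an alternative added after seeing the data, the ratio for gene bodies turned to 0.981 and the other 2 classes kept their direction. The density ratio of chromosome 15 to chromosome 6 fell from 20.3 to 10.8 and 11.03 at the stricter settings, with intervals that include 20.3. The count of gene lists with a called gene-end share was 0, but 1 with a window of 3000 bp, namely spliceosome and RNA processing, with 6 of 26 genes against 5.10% of others (adjusted p = 0.044, Fisher's exact test). The count called by nearest gene was 1, but 0 at a q of at most 0.001 and 0 at 5-fold or more, where 1 gene of that list was left. Against random lists the ratio was 3.20 (1.68 to 4.95) in the full list, 11.7 (0.297 to 59.9) at the q limit, with 0.0853 genes expected, and 8.18 (0.207 to 41.8) at 5-fold, with 0.122 expected. The calls ended with the fall in the number of peaks, and these intervals do not show whether the ratio changed. The strength of gene-end peaks passed no test at any setting run, and with means in place of the tied median folds, added after seeing the data, gene-end peaks differed from the rest by -0.0474 in fold (permutation p = 0.0734) and -0.0562 in −log10 p (p = 0.351). The other alternatives that were run left every result named in the comparisons on its side of the threshold. Not run were the motif searches, the removal of repeat-rich peaks and the authors' annotation. No paired analysis was possible because each kind of library was represented by 1 sample. The median summit holds 10 tags, and whether deeper libraries would give more peaks was not tested.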

Other observations

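The tests of copy number by background, of RNA processing genes by the product of territory and local density and of the weakest peaks against shifted summits, and the simulations, were chosen only after the result was seen. The shift of all summits, the test of gene density over blocks and the matching of RNA processing genes on territory and density each were also added after the data had been seen, but their outcomes were written down before they were run. The tests of gene density over chromosomes, of raised input and of peak strength had their outcomes written down before they were run.

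Among the coding genes with the most peaks inside them, Nrxn3, a synaptic adhesion gene of 1612 kb, held 14 peaks, 8.68 per Mb against 5.76 for its chromosome 12. It lies across the 10 Mb bins from 80 and 90 Mb, which held 71 and 98 peaks, so its density is close to that around it. Ptprn2, on the same chromosome, held 12 peaks (15.1 per Mb) and lies in the bin from 110 Mb, with 98 peaks. Dmd, the dystrophin gene, held 9, and its 3.77 per Mb is close to the 3.82 of chromosome X. Nbea held 10, or 17.9 per Mb against 3.66 for chromosome 3, and lies in a block where the 10 Mb bin from 50 Mb held 65 peaks. Slc7a11 was the nearest coding gene of 7 peaks and lies in the same part of chromosome 3. These genes were picked after their values were seen, and no test was run on them.

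The first pattern is the uneven density over chromosomes and blocks. Between chromosomes, gene density as the whole cause is argued against by chromosome 7, which has 13.97 coding genes per Mb but 1.05 peaks per Mb, while chromosome 12 has 5.66 and 5.76, and by a Spearman rho of -0.191 (permutation p = 0.421; Pearson r -0.085, p = 0.726, and 0.058 without the 2 chromosomes farthest from the median gene density). Within chromosomes gene density stays open, since peaks rose with coding genes over 517 bins of 5 Mb, with a rank correlation of 0.470 (95% interval 0.412 to 0.522, permutation p = 1e-04, the smallest 10000 permutations give), which met neither the 0.5 nor the 0.3 written down before the run. The DNA copy number of the line is a candidate explanation for which regions are dense: denser chromosomes had a smaller share of peaks at the genome-wide background, so the input set the background of more of them, with a rho of -0.826 (Pearson r -0.784, and -0.709 without the 2 chromosomes farthest from the median density; permutation p = 5e-05 for both, the smallest 20000 permutations give), and the share fell from 65.2% in 5 Mb bins of 5 to 10 peaks to 33.6% in bins of over 30 (within-chromosome rho -0.359, permutation p = 1e-04). Any other megabase-scale rise of input coverage, as in gene-rich blocks, would look alike, and no biological explanation was tested.

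With coverage changed alike in both libraries, tags placed at random did not reach the density of the dense chromosomes. Chance peaks numbered 0.015 per Mb at 0.75 times the average, 0.23 at the average (95% interval 0.168 to 0.307), 0.28 at 1.25 times, 0.205 at 1.5 times and 0.175 at 2 times, against 6.38 on chromosome 15. The value at the average amounts to 430 peaks over the effective genome and that at 0.75 times to 28, against 7680 in the list. Chromosome 6 had 0.314 per Mb of annotated span (0.231 to 0.418). That interval overlaps the one of chance peaks at the average and lies above the one at 0.75 times (0.00309 to 0.0438). Chromosome 10 had 0.455 (0.345 to 0.588), above both. Whether chromosome 6 is at chance level thus depends on the coverage assumed. The shares of peaks at the genome-wide background on chromosomes 6 and 10 were 70.2% and 62.1%. Among chance peaks this share was 32.6% at the average and 66.7% at 0.75 times, the latter of only 3 chance peaks. With shared coverage of 1.25, 1.5 and 2 times the share was 1.79%, 0% and 0%, against 36.8% and 38.9% on the dense chromosomes 12 and 15. The simulated average rests on the header's effective genome size, and the annotated spans of the chromosomes are longer. These settings therefore cannot be matched to gains in the line, and no conclusion on a shared gain is drawn from that share. Coverage raised in the ChIP alone by 1.25 and 1.5 times gave 2.08 and 9.56 per Mb, with 40.9% and 35.3% at that background. In these simulations no shared change in coverage reached the number of peaks on dense chromosomes. Relative density did change, from 0.015 per Mb at 0.75 times (3 chance peaks) to 0.28 at 1.25 times. The simulated coverage is even and set by the header's effective genome size. For both reasons the simulations do not exclude a shared change in copy number.

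The second pattern is the excess at gene ends. Position in gene-rich or dense neighbourhoods is argued against as the whole cause by the ratio of 1.41 (1.29 to 1.55) over summits shifted by 10000 bp. Regions of raised input, such as repeats, are argued against as the whole cause by a ratio of 1.503 (1.34 to 1.68) among the 3784 peaks at the genome-wide background. The interval of that ratio excludes values under 1.2, where raised input would have been the whole cause, but it does not clear the stricter bound of 1.5 written beforehand. Among the rest the ratio was higher, at 1.83, so a part from raised input stays open. The share at gene ends did not grow with peak strength. It was 8.26% in the weakest 1913 peaks by p and 6.95% in the strongest, a difference of -1.31 percentage points (95% interval -2.996 to 0.377, Fisher's exact p = 0.143). That the weakest of these peaks are all chance, evenly placed in their neighbourhoods, is argued against by a ratio of 1.463 (1.204 to 1.778) over the same summits shifted by 10000 bp, at 8.26% against 5.65%. How large a part of them is chance stays open, since a mixture would also give such a ratio. Base composition, enzymatic digestion of open chromatin and Nr4a2 binding all stay open and were not tested here.

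The third pattern is the RNA processing list. Local density and gene territory are argued against as the whole cause by an adjusted permutation p of 0.0468 against lists matched on their product (exact 0.037), and by an adjusted exact p of 0.038 against lists matched on each, where the ratio was 2.62 (1.38 to 4.05) against 3.20 (1.68 to 4.95) with territory alone. The call ended at a q of at most 0.001 and at 5-fold or more, both with an adjusted permutation p of 1. Other lists of broadly transcribed genes varied, with 5 of 46 ribosomal protein genes against 5.06 in matched random lists, 4 of 40 oxidative phosphorylation genes against 4.97, and 7 of 21 unfolded protein response and heat shock genes against 2.92 (unadjusted permutation p = 0.025), and differences between lists were not tested. Binding of Nr4a2 near splicing genes is a hypothesis that may be worth a replicated test. Open chromatin at these genes stays open as well, since expression was not measured here.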
